A study of Homo sapiens with 12 samples.

How the data were processed

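Mature miRNAs were measured by small RNA sequencing in 12 libraries of cultured human primary melanocytes, in 4 groups of 3 defined by the growth medium (with or without TPA) and by doxycycline induction of BRAF V600E. RNA was extracted with Trizol and libraries were made with a Qiagen miRNA kit. The deposited table holds expected counts per mature miRNA, not scaled to library size. Of the values above 0, 62.6% were whole numbers within 0.005, and 88.8% lay near a multiple of a twelfth by a wider tolerance. The submitters' processing notes name STAR 2.7.2c, featureCounts 1.6.3 of Subread 1.6.3 and the genome build GRCh38. The miRBase release, the counting settings and any use of molecular identifiers were not given in the sources used here. The series design text describes skin and nevus cultures, which are not among these samples and are not analysed here.

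The table's columns and the sample descriptions carry different request numbers, each followed by a library number; columns were assigned to samples by library number, which is an assumption. Of 2652 miRNAs, 1003 had no count in any library. Library totals ran from 3134479 to 6792934 counts. Between replicates of a group, chi-square per degree of freedom over miRNAs with at least 20 counts in the pair ran from 59.5 to 218, so the spread between libraries exceeded counting error. Where a group had no counts, a floor of 3 counts over the group gave a rough lower bound, and 95% intervals of count ratios cover counting error only. Genome locations came from GENCODE annotation of GRCh38, which matched 2572 of the 2652 miRNAs by mature name.

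Counts were rounded to whole numbers for the tests. edgeR 4.0.16 (R 4.3.3, limma 3.58.1) was used with TMM scaling, filterByExpr by group, and a quasi-likelihood F test on all 12 libraries in one fit with a coefficient per group. The filter kept 531 miRNAs, which held 99.97% of counts, and TMM factors ran from 0.824 to 1.238. Printed CPM values are scaled by these factors and given as mean ± SD over the 3 libraries of a group; fold changes come from the fit unless called ratios by counts. There were 5 comparisons: the BRAF effect with and without TPA, the TPA effect with and without BRAF, and the interaction, which is the test of the difference between the BRAF effects. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05.

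Before the data were examined, the groups, the tests, 26 lists of related miRNAs and the rule for named miRNAs were fixed. The rule took, per comparison, the 10 largest rises and the 10 largest falls among called miRNAs averaging at least 10 CPM whose groups did not overlap, the 5 largest interactions in each direction, miR-211-5p and miR-328-3p throughout, and up to 4 of the most abundant members of each list. miRNAs named outside it, such as the shared calls, the other interaction calls and the markers miR-143-3p and miR-214-3p, were chosen after their values were seen. The rule had named miR-145-5p, but its sum with those markers was also chosen afterwards. Lists with at least 3 tested members were tested by camera in limma with a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation; members were also counted after adjusting over the list alone.

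The alternatives were RLE, upper-quartile or no composition factors, no filter or a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, a fit of the compared groups only, a replicate block, removal of the most abundant miRNA and each library left out in turn. Alternatives added after the data were seen were fractional counts, thinning to the smallest library (3134476 counts) and removal of the 14q32 and mesenchymal miRNAs. Replicate numbers were checked as a pairing: over 18 pairs with the same number, the median correlation of residuals was 0.006, so they were not used as pairs. The pipeline was tested on simulated data. For the BRAF effect with TPA it recovered 35.8% of 1.5-fold, 70.1% of 2-fold and 89.4% of 4-fold changes and called 1.8% of unchanged miRNAs. For the interaction the figures were 22.4%, 46.3%, 84.8% and 0.9%. The simulation changed 67, 67 and 66 miRNAs at those sizes, in TPA with BRAF only, and left 331 unchanged. It held no other difference between the groups. More miRNAs were changed than the real comparisons called (31 and 15), so recovery in the real data may be lower. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.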

Results

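Small RNA libraries were sequenced from cultured human primary melanocytes, the pigment-producing cells of the skin, that carried a doxycycline-inducible BRAF V600E, an activated form of a kinase in the ERK signalling pathway. The 12 libraries fell into 4 groups of 3: medium with TPA without doxycycline (TPA no BRAF), medium with TPA and doxycycline (TPA with BRAF), medium without TPA or doxycycline (No TPA no BRAF), and medium without TPA but with doxycycline (No TPA with BRAF). TPA is a phorbol ester that activates protein kinase C and is a common mitogen in melanocyte media. Doxycycline was given for 4 days at 15 ng/uL, as the labels state. No group had doxycycline without the BRAF insert, so each BRAF effect below is that of doxycycline and the induced gene together. The labels name different growth supplements for the media with and without TPA, so each TPA effect holds any other difference between the supplements.

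The count table listed 2652 mature miRNAs. Total counts per library ran from 5155632 to 6792934 with TPA and from 3134479 to 4546809 without. The most abundant miRNA, miR-146a-5p, took 32.1% ± 0.667 of counts in TPA no BRAF, 27.9% ± 1.56 in TPA with BRAF, 14.8% ± 1.16 in No TPA no BRAF and 15.5% ± 0.575 in No TPA with BRAF (mean ± SD, n = 3 libraries each). The table's columns carry a different sequencing request number from the sample descriptions, and libraries were matched by the library number that follows it. Every comparison rests on that match. The labels do not say whether the 3 replicates of a group were separate cultures or donors, so each test measures the spread between these libraries only. In a principal component analysis, the first component held 61.4% of the variance and parted the media, with values from -12.9 to -10.41 with TPA and from 9.9 to 14.15 without. The second component, with 11.4%, parted the BRAF groups without TPA, while replicate 2 of TPA no BRAF and replicate 2 of TPA with BRAF lay almost together at -0.15 and -0.16.

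**Figure D1:**
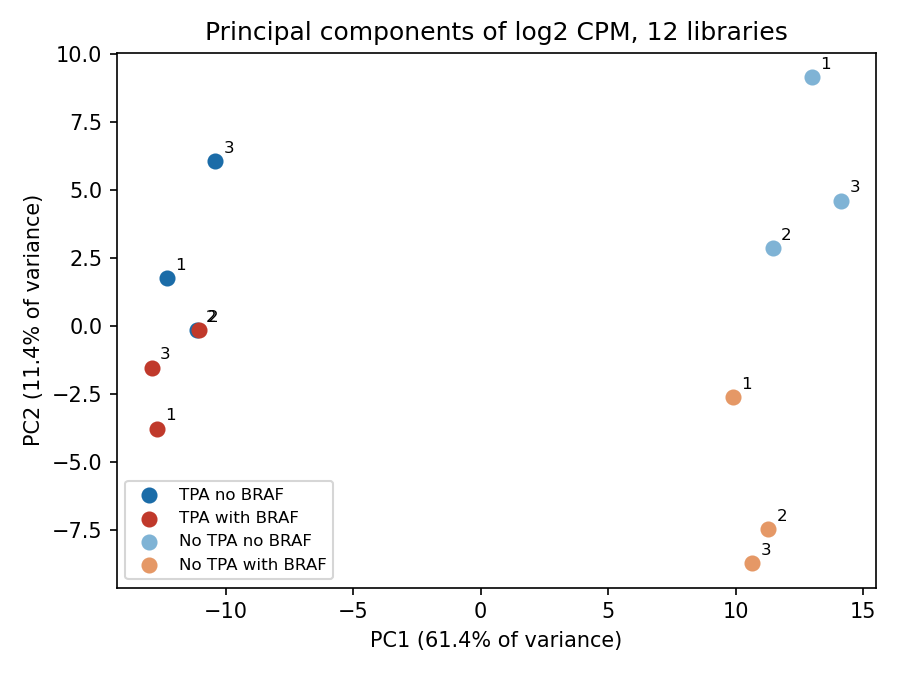
Principal component 1 (x axis, 61.4% of variance) against principal component 2 (y axis, 11.4% of variance) of log2 CPM; each point is a library, coloured by group and numbered by replicate. All libraries with TPA lie at or below -10.41 on the first component and all libraries without TPA at or above 9.9.

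The first comparison asked how induced BRAF V600E altered miRNAs in medium with TPA, in a study concerned with miRNAs that restrain growth in BRAF V600E nevi. miR-31-5p had the largest rise among called miRNAs with a mean of at least 10 CPM (counts scaled to library size with TMM factors): it went from 928 ± 147 to 4186 ± 758 CPM (mean ± SD, n = 3), a 4.51-fold rise (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.22e-08), with all 3 BRAF libraries above all 3 others. Its precursor MIR31 lies on GRCh38 chromosome 9 from 21512115 to 21512185, in an intron of MIR31HG, and the other arm, miR-31-3p, rose 4.40-fold. Of the 16 tested members of the growth-factor and ERK/AP-1 responsive list, 10 rose and none fell (11 rose when adjusted over the list alone), among them miR-221-3p 2.42-fold, miR-222-3p 2.29-fold and miR-21-5p 1.70-fold. miR-221 and miR-222, known to target the cell-cycle inhibitor p27, lie side by side on chromosome X, with MIR221 from 45746157 to 45746266 and MIR222 from 45747015 to 45747124. That list passed camera (adjusted p = 8.9e-11), and did so with an estimated correlation (adjusted p = 0.00688).

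Of the 11 tested members of the list of miR-99, miR-100 and miR-125 clusters, 4 rose (4 when adjusted over the list alone): miR-125b-1-3p 4.16-fold, miR-100-3p 3.86-fold, miR-100-5p 3.08-fold and miR-125b-5p 2.10-fold. MIR100 (chromosome 11, 122152229 to 122152308) and MIR125B1 (122099757 to 122099844) lie in introns of MIR100HG; miR-125b-5p is also made from MIR125B2 on chromosome 21. The list did not pass camera (adjusted p = 0.23), and its median log2 change was -0.13 while its mean was 0.47. miR-187-3p rose 4.37-fold and miR-135b-5p 3.17-fold. Low values underlie the rises of miR-187-3p (from 2.55 ± 1.24 to 11.2 ± 3.04 CPM) and of miR-125b-1-3p (from 2.07 ± 1.24 to 8.76 ± 1.08 CPM, n = 3 each). Of the 4 tested fibroblast and mesenchymal markers, miR-199a-3p rose 1.68-fold and miR-199b-5p 1.51-fold, and the list did not pass camera (adjusted p = 0.23). In the X-linked miR-506-514 list, 3 of 20 fell (8 when adjusted over the list alone): miR-513b-5p was 1.67-fold, miR-513a-5p 1.66-fold and miR-509-5p 1.43-fold lower. That list passed camera (adjusted p = 2.08e-05) but not with an estimated correlation (adjusted p = 0.0603).

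The miRNAs that the study names as acting on the mitotic kinase AURKB did not pass the test here when adjusted over all 531 miRNAs; adjusted over the list alone, 2 of 3 fell, both arms of miR-211 (camera adjusted p = 0.254), and the same 2 of 3 in the melanocyte lineage list (camera adjusted p = 0.261). miR-211-5p, whose precursor MIR211 (chromosome 15, 31065032 to 31065141) lies in an intron of the melanocyte gene TRPM1, stood at 12195 ± 1719 CPM without and 8407 ± 1890 with BRAF (n = 3 each), a log2 change of -0.54 (edgeR quasi-likelihood test, adjusted p = 0.161). miR-211-3p went from 159 ± 12.4 to 94.96 ± 18.8 CPM (n = 3 each), a log2 change of -0.74 (edgeR quasi-likelihood test, adjusted p = 0.0558), and was called with DESeq2, with limma-voom, with no filter, in a fit of the compared groups only and without TPA with BRAF replicate 2. miR-328-3p, from MIR328 on chromosome 16 (67202321 to 67202395), stood at 55.0 ± 7.62 and 58.8 ± 6.49 CPM, a log2 change of 0.10 (edgeR quasi-likelihood test, adjusted p = 0.856). In all, 31 of 531 tested miRNAs passed, 25 higher and 6 lower; with all libraries kept, the number lower ran from 1 without the 14q32 and mesenchymal miRNAs to 16 with DESeq2 (28 higher). The count fell to 20 without TPA no BRAF replicate 1, to 19 without TPA with BRAF replicate 2 and to 18 without TPA with BRAF replicate 3. Each of the 6 falls lost its call under at least 1 alternative, and miR-199b-5p lost its call with upper-quartile factors and when any of 5 of the 6 libraries was left out.

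**Figure D2:**
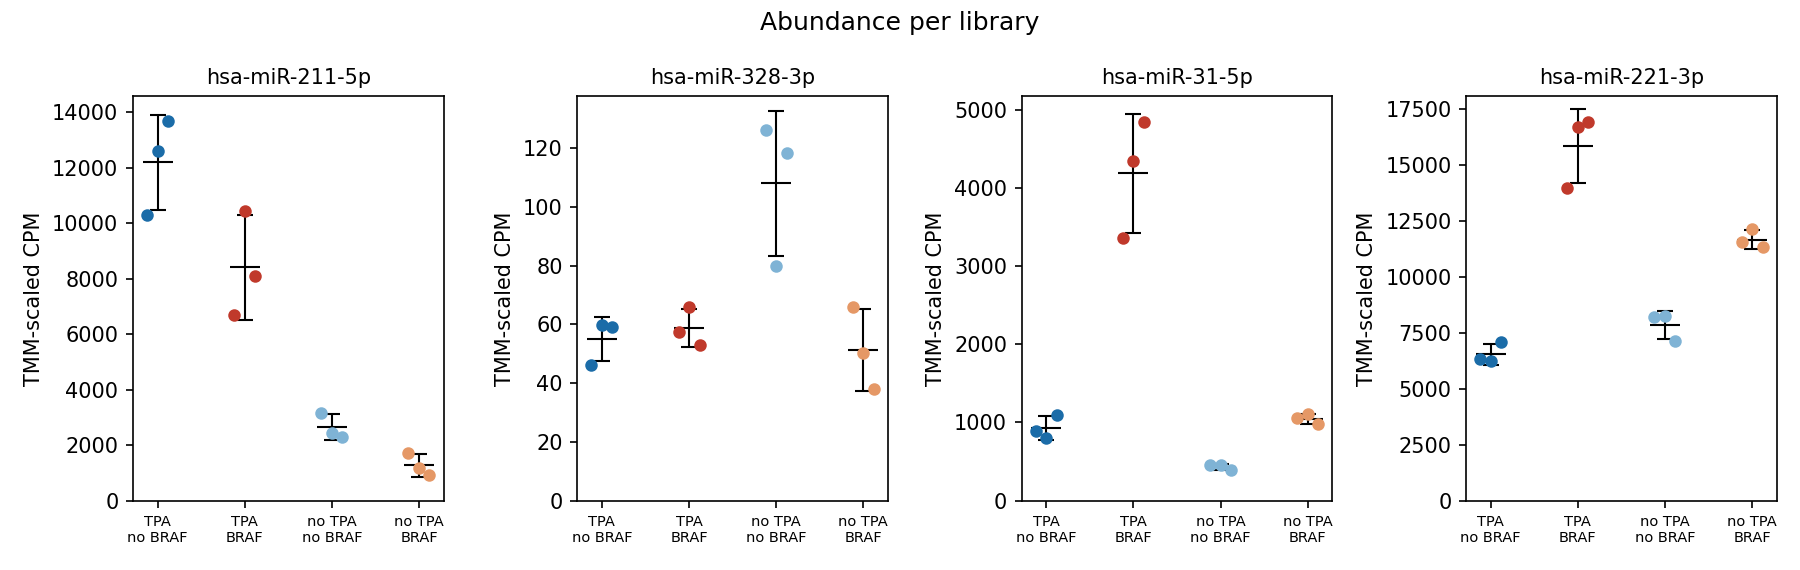
Abundance of miR-211-5p, miR-328-3p, miR-31-5p and miR-221-3p (y axes, TMM-scaled CPM, each from 0) in the 4 groups (x axes); points are the 3 libraries of a group, and black bars the mean and SD. miR-31-5p reached 4186 CPM in TPA with BRAF, and miR-211-5p was lowest in No TPA with BRAF at 1271 CPM.

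The second comparison asked the same question in medium without TPA. There, miR-211-5p fell from 2636 ± 467 to 1271 ± 414 CPM and was 2.07-fold lower, and miR-328-3p fell from 108 ± 24.8 to 51.4 ± 13.98 CPM and was 2.10-fold lower (n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00441 for both), each with all 3 BRAF libraries below all 3 others. miR-211-3p was 1.99-fold lower. All 3 tested members of the study's list fell (3 when adjusted over the list alone); the study chose that list partly on these samples, so this is not independent evidence of its direction. Of the 3 tested members of the melanocyte lineage list, 2 fell (2 when adjusted over the list alone), both of them arms of miR-211. The study's list passed camera (adjusted p = 0.0325), as did the melanocyte lineage list (adjusted p = 0.0469), but neither did with an estimated correlation (adjusted p = 0.428 and 0.439). Of the 5 tested keratinocyte and epithelial markers, 1 rose (2 when adjusted over the list alone; camera adjusted p = 0.613), and their summed abundance was 52.8 ± 1.68 CPM without and 92.7 ± 37.0 with BRAF (n = 3 each). The called one, miR-203a-3p, was 2.02-fold higher, a call that ended with limma-voom, with a replicate block and when any of 5 of the 6 libraries was left out.

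Among the rises without TPA, miR-31-3p went up 3.54-fold, miR-31-5p 2.41-fold, miR-222-5p 2.97-fold, miR-100-3p 3.34-fold and miR-7-5p 2.06-fold. Libraries spread widely for miR-100-3p, at 150 ± 99.9 CPM without and 501 ± 232 CPM with BRAF (n = 3 each). miR-155-5p, a miRNA tied to NF-kB signalling, rose 2.68-fold from 217 ± 12.7 to 582 ± 93.4 CPM (n = 3 each), and miR-577 rose 2.67-fold. In the growth-factor and ERK/AP-1 list, 7 of 16 rose and 2 fell (8 and 2 when adjusted over the list alone). In the NF-kB and inflammation list, 1 of 7 rose (2 when adjusted over the list alone). Both passed camera (adjusted p = 0.0469 for each) but not with an estimated correlation (adjusted p = 0.417 for each). In the X-linked miR-506-514 list, 4 of 20 fell (7 when adjusted over the list alone), with miR-509-3p 1.70-fold lower, a call that ended without No TPA no BRAF replicate 1 or No TPA with BRAF replicate 3; camera gave adjusted p = 0.0346, and adjusted p = 0.417 with an estimated correlation. miR-199b-5p, on the fibroblast and mesenchymal list, rose 1.76-fold. miR-181a-2-3p was 2.02-fold lower, miR-129-5p 2.03-fold and miR-3609 2.49-fold lower. miR-1291 was 2.95-fold and miR-1248 3.09-fold lower, and their precursors overlap the small nucleolar RNAs SNORA2C and SNORA81 on the same strand.

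In this comparison 80 of 531 miRNAs passed, 31 higher and 49 lower. The 2 BRAF comparisons share no libraries. In both, 13 miRNAs were higher, against 1.46 expected if the calls were independent. Among the 13 were both arms of miR-31, miR-221 and miR-222. All 12 libraries were fitted together with a shared spread per miRNA, so expected numbers here are not strict chance levels. For falls, 1 was shared (miR-509-5p) against 0.55 expected, miR-132-3p was called in opposite directions, and across miRNAs, which are not independent replicates, the log2 changes had Pearson's r = 0.244. The count fell to 33 without No TPA no BRAF replicate 1, which also ended the call of miR-1248, to 34 without No TPA with BRAF replicate 2 and to 37 without No TPA with BRAF replicate 3. miR-211-3p lost its call when any of these 3 libraries was left out. The larger share of falls did not hold throughout, and more miRNAs were higher than lower when the counts were thinned to the smallest library (49 and 34), with DESeq2 (56 and 48), with RLE factors (42 and 41), with a mean of at least 10 CPM (46 and 40) and with no filter (47 and 44).

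The third comparison asked what TPA medium did to melanocytes without BRAF. The miRNAs of the 14q32 imprinted cluster, a run of miRNA genes on chromosome 14 read from the maternal copy, were nearly absent with TPA: their summed abundance was 10.7 ± 1.27 CPM with TPA and 156 ± 13.8 CPM without (n = 3 each). That sum covers all 92 miRNAs of the list. Of these, 19 passed the filter, mainly through their counts without TPA, which favours falls in the member count and the list test. Of the 19 tested members, 18 were lower with TPA (18 when adjusted over the list alone). The exception, miR-494-3p, had a log2 change of -0.93 (edgeR quasi-likelihood test, adjusted p = 0.122). Their precursors lie on chromosome 14 between 100869060 and 101065378. miR-127-3p was 22.3-fold lower by counts (95% interval 13.1 to 41.3), from 279 counts over the 3 libraries without TPA to 14 with it. miR-654-3p went from 89 counts to 0 with TPA, a 33.2-fold fall by a floor of 3 counts over the group. Its lower 95% limit by counts was 26.4-fold. Such intervals and limits cover counting error only. The list passed camera (adjusted p = 1.98e-11), and did so with an estimated correlation (adjusted p = 0.0147). On the fibroblast and mesenchymal list, miR-199a-3p was 2.42-fold and miR-199b-5p 2.03-fold lower with TPA, while miR-143-3p stood at 1.89 ± 0.53 CPM with and 1.57 ± 0.5 CPM without it (n = 3 each).

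miR-211-5p was 4.63-fold higher with TPA, at 12195 ± 1719 against 2636 ± 467 CPM (n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.16e-07), and miR-211-3p was 4.37-fold higher, whereas miR-328-3p was 1.96-fold lower (adjusted p = 0.00122). Of the 7 tested NF-kB and inflammation miRNAs, 6 rose and 1 fell (the same counts when adjusted over the list alone): miR-146a-5p, a negative regulator of NF-kB signalling (MIR146A, chromosome 5, 160485352 to 160485450), rose 3.09-fold, miR-9-5p 2.96-fold and miR-155-5p 2.68-fold, while miR-187-3p was 6.66-fold lower. The list passed camera (adjusted p = 0.00323) but not with an estimated correlation (adjusted p = 0.177). miR-122-5p, known for its abundance in liver, was 5.08-fold higher at 20.4 ± 6.24 CPM, and miR-31-3p was 3.31-fold higher.

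Besides 14q32, 3 lists were lower with TPA by camera with adjusted p = 0.0132 each, none of them with an estimated correlation. In the miR-23/27/24 list 6 of 10 fell (7 fell and 1 rose when adjusted over the list alone; adjusted p = 0.177 with an estimated correlation), with miR-27b-3p 2.68-fold lower. In the miR-181 list 5 of 9 fell (5 when adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), with miR-181a-2-3p 4.64-fold lower. In the list of miR-99, miR-100 and miR-125 clusters 7 of 11 fell (7 when adjusted over the list alone; adjusted p = 0.177 with an estimated correlation), with miR-125b-5p 3.79-fold and miR-100-5p 3.68-fold lower. Other large falls were miR-708-5p at 7.06-fold, miR-137-3p, a miRNA known to target the melanocyte regulator MITF, at 5.51-fold, and miR-503-5p at 4.61-fold lower. In all, 244 of 531 miRNAs passed, 112 higher and 132 lower; without No TPA no BRAF replicate 1, 70 were higher and 135 lower. With library totals only, the median of all miRNAs shifted by -0.51 (log2) and 43 were higher and 250 lower, so directions here are relative to the TMM scaling. Of the 244 calls, 69 were lost with library totals and 12 had the opposite sign, among them miR-93-5p, miR-25-3p and miR-10a-5p. The other called miRNAs named in the paragraphs on this comparison were not among those 12.

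**Figure D3:**
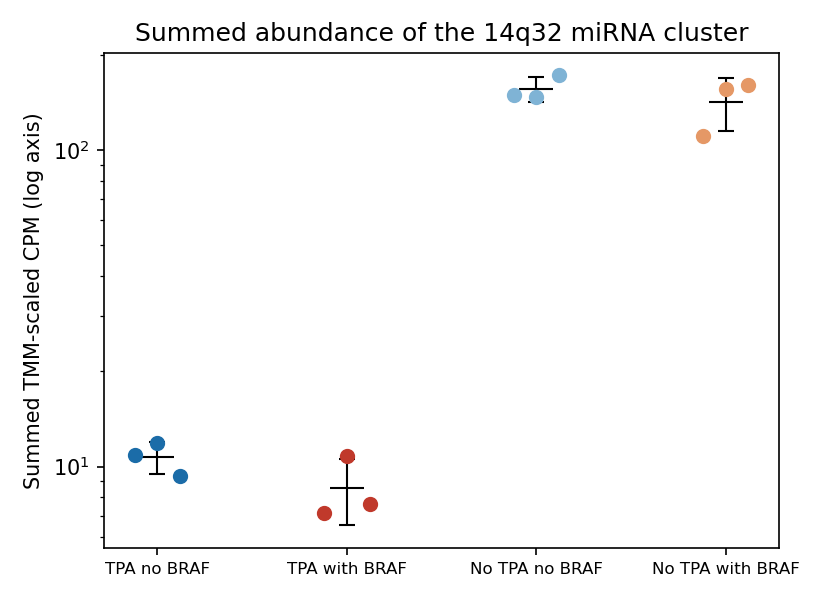
Summed TMM-scaled CPM of the 14q32 cluster miRNAs (y axis, log scale) in the 4 groups (x axis); points are libraries, and black bars the mean and SD of 3 libraries. The libraries with TPA lie between 7.14 and 11.9 CPM and those without between 110 and 172 CPM.

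The fourth comparison asked the same of TPA medium in cells with induced BRAF. miR-211-5p was 6.62-fold higher with TPA, at 8407 ± 1890 against 1271 ± 414 CPM (n = 3 each; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.43e-08), and all 3 tested melanocyte lineage members were higher (3 when adjusted over the list alone). That list passed camera (adjusted p = 0.0184; adjusted p = 0.266 with an estimated correlation), and the call of its remaining member, miR-204-5p, at 1.54-fold, ended under library totals and without TPA with BRAF replicate 2 or No TPA with BRAF replicate 2 or 3. The study's list had 2 of 3 higher (2 when adjusted over the list alone), which is not independent evidence since the study chose it partly on these samples, and passed camera (adjusted p = 0.0342; adjusted p = 0.338 with an estimated correlation). miR-328-3p had a log2 change of 0.20 (edgeR quasi-likelihood test, adjusted p = 0.523). miR-132-3p, a miRNA induced by the transcription factor CREB, was 4.94-fold higher, miR-31-5p 4.00-fold, miR-196b-5p 3.47-fold and miR-146a-5p 2.35-fold higher.

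The 14q32 cluster was again lower with TPA, at 8.53 ± 2.01 against 142 ± 27.4 CPM (n = 3 each). Of its 19 tested members, which passed the filter mainly through their counts without TPA, 18 were called (19 when adjusted over the list alone). The cluster passed camera (adjusted p = 1.63e-13), and did so with an estimated correlation (adjusted p = 0.00821). miR-199a-3p was 1.87-fold and miR-199b-5p 2.36-fold lower. In the list of miR-15, miR-16, miR-195, miR-497, miR-424, miR-503, miR-450 and miR-542 members, 12 of 21 fell and 2 rose (12 and 2 when adjusted over the list alone). miR-503-5p was 4.47-fold and miR-424-5p 3.86-fold lower. The list's falls shared by both TPA comparisons were arms of miR-424, miR-450a, miR-450b, miR-497, miR-503 and miR-542. No arm of miR-15a, miR-15b or miR-16 was among them. miR-15a-5p rose 1.29-fold but had a log2 change of -0.008 under library totals, and its call ended under several other alternatives. That list passed camera (adjusted p = 0.00287; adjusted p = 0.183 with an estimated correlation). The NF-kB and inflammation list had 6 of 7 higher and 1 lower (the same counts when adjusted over the list alone; camera adjusted p = 0.00484; adjusted p = 0.183 with an estimated correlation). In the miR-181 list 5 of 9 fell (5 when adjusted over the list alone; camera adjusted p = 0.033; adjusted p = 0.266 with an estimated correlation), and in the list of miR-99, miR-100 and miR-125 clusters 8 of 11 fell (8 when adjusted over the list alone; camera adjusted p = 0.0376; adjusted p = 0.266 with an estimated correlation). miR-708-5p was 9.71-fold and miR-137-3p 5.57-fold lower.

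Here 219 of 531 miRNAs passed, 101 higher and 118 lower. Across the TPA comparisons, which share no libraries, 69 miRNAs were higher in both against 21.3 expected if the calls were independent. In both, 93 were lower against 29.3 expected. These calls too come from the fit with a shared spread per miRNA, so the expected numbers are not strict chance levels. Across miRNAs the log2 changes had Pearson's r = 0.863. Library totals shifted the median by -0.39 (log2) and gave 50 higher and 190 lower.

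The last comparison asked whether the BRAF effect differed between the media. miR-132-3p went from 90.9 ± 27.3 to 151.8 ± 20.1 CPM with BRAF in TPA medium and from 52.8 ± 5.62 to 30.8 ± 5.81 CPM without TPA (n = 3 each), a difference between log2 changes of 1.52 (edgeR quasi-likelihood test of the interaction, Benjamini-Hochberg adjusted p = 0.0236). The rise of miR-31-5p was larger with TPA by 0.90 (log2) and that of miR-221-3p by 0.71. miR-187-3p differed by 1.99, as it rose with TPA but had no called change without it (log2 change 0.14, edgeR quasi-likelihood test, adjusted p = 0.782). miR-577 and miR-335-5p went the other way, with differences of -1.71 and -1.24. miR-328-3p differed by 1.17 (edgeR quasi-likelihood test of the interaction, adjusted p = 0.0433; from 0.00252 to 0.138 over 24 alternatives, of which 11 kept the call), and miR-211-5p by 0.52 (adjusted p = 0.35), so its BRAF effect was not shown to differ between the media. Of the 16 growth-factor and ERK/AP-1 miRNAs, 4 had a higher log2 change with BRAF in TPA medium than without TPA (6 when adjusted over the list alone; camera adjusted p = 0.00167; adjusted p = 0.209 with an estimated correlation). In all 15 miRNAs passed, 11 with a higher and 4 with a lower change with TPA; the majority turned with DESeq2 (19 and 30) and with thinned counts (6 and 8), and RLE factors gave 11 and 9. The edgeR count was 0 when any of 6 libraries was left out (TPA no BRAF replicate 1; TPA with BRAF replicates 2 and 3; No TPA no BRAF replicate 1; No TPA with BRAF replicates 2 and 3), with from 77 to 92 miRNAs at an unadjusted p under 0.05. It was 1 without TPA no BRAF replicate 2, 4 without No TPA no BRAF replicate 3, 24 without No TPA with BRAF replicate 1 and 36 without TPA no BRAF replicate 3.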

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

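The tests in this part on the 14q32 cluster, on small nucleolar RNA overlaps, on weaker induction and on other splits of the samples were chosen after the result was seen; the test for a mislabelled library was set before its result. The BRAF effect differed between the media, by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment, for 15 miRNAs. As the log2 change with BRAF in TPA medium minus that without TPA, the difference was positive for miR-187-3p (1.99), miR-132-5p (1.94), miR-1249-3p (1.87), miR-132-3p (1.52), miR-149-5p (1.44), miR-92b-5p (1.32), miR-92b-3p (1.28), miR-328-3p (1.17), miR-23b-3p (0.95), miR-31-5p (0.90) and miR-221-3p (0.71). It was negative for miR-155-5p (-0.82), miR-335-5p (-1.24), miR-577 (-1.71) and miR-3662 (-2.21).

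Other splits of the libraries were counted for each comparison. For the pairwise comparisons there are 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05; in each, only the real split (1 of the 10) gave its count, which was 31 for the BRAF effect with TPA, 80 for that without TPA, 244 for the TPA effect without BRAF and 219 for that with BRAF. The highest count of the other splits was 0 each time by edgeR, with up to 58, 68, 60 and 33 miRNAs at an unadjusted p under 0.05. Those splits mix the real groups, and the spread was refitted for each, so a real difference widens it. Their low counts are therefore no independent support for the real grouping. For the interaction, 5 of 100 splits, the real one included, gave 15 or more miRNAs, so chance is not excluded; the highest of the others gave 72. That split swaps the doxycycline labels in a single medium, so it measures the sum of the BRAF effects, which is a structure of the samples. The 5 of 100 include it, so their share does not measure chance alone.

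The 14q32 cluster was lower with TPA in both TPA comparisons. Fibroblast or mesenchymal cells in the cultures without TPA would raise their abundant miRNAs too. The summed CPM of miR-143-3p, miR-145-5p and miR-214-3p, a sum chosen afterwards, was 3.93 with and 3.33 without TPA. That is a rise of -0.43% of that of the cluster. The whole fibroblast and mesenchymal list rose without TPA, through miR-199a-3p and miR-199b-5p. Its sum went from 206 ± 27.6 with to 429 ± 69.0 CPM without TPA in cells without BRAF (n = 3 each). In cells with BRAF it went from 315 ± 5.71 to 705 ± 21.5 CPM (n = 3 each). The sums disagree, so such cells are not excluded. Scaling is argued against by a median log2 change no nearer to 0 than -4.42 over 4 scalings; the libraries with TPA had the higher total counts. Fibroblast or mesenchymal cells may account for it. A response to TPA or to another part of the supplement, or growth of a subset of melanocytes in either medium, may also do so. All of these stay open.

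Of the 49 miRNAs lower with BRAF without TPA, miR-1248 and miR-1291 overlap small nucleolar RNAs. Of the other lower miRNAs, 45 overlap no annotated small RNA of another class and 2 had no location, so their overlap is not known. Among tested miRNAs with a location, 33.3% of 6 that overlap were lower against 8.7% of the rest (Fisher's exact test, two-sided, p = 0.0933), and with so few the sources cannot be told apart. Fragments of such RNAs counted as miRNAs, or a change in the miRNAs themselves, stay open.

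Without TPA, replicate 1 with BRAF lay nearest to the libraries without BRAF on the second component (-2.61, against -7.49 and -8.74 for the other two), and leaving it out raised the count from 80 to 91. A mislabelled library is argued against by a score from the 25 higher and 6 lower miRNAs of the BRAF effect with TPA, which uses other libraries: it lay 0.619 above the highest library without BRAF, whose group had an SD of 0.094. A weaker induction is argued against, for the miRNAs of the score only, as its score lay at -0.031 from the lower of the other 2 BRAF libraries. For miR-211-5p, which fell with BRAF, replicate 1 stood highest of its group, at 1728 against 1161 and 923 CPM. The same held for miR-328-3p, at 65.8 against 50.4 and 37.9 CPM. For these falls a weaker effect in that library is not excluded. What sets that library apart stays open.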

How the results depend on the processing

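Of the alternatives tested, fractional counts, thinning, and removal of the 14q32 and mesenchymal miRNAs were chosen after the result was seen; the others were fixed beforehand. Counts of called miRNAs stayed within 1.5 times their value under every alternative that kept all libraries, except the interaction (15), which gave 49 with DESeq2, 38 with no filter and 9 with a replicate block. Leaving out a library gave 18 to 27 for the BRAF effect with TPA (31), 33 to 91 for that without TPA (80), 205 to 241 for the TPA effect without BRAF (244), 178 to 193 for that with BRAF (219) and 0 to 36 for the interaction. A fit with fewer libraries has less power; beyond that the cause was not tested. With an estimated correlation, camera called 1 list for the BRAF effect with TPA (2 with the preset value), 0 for that without TPA (5; 0 also at an unadjusted p under 0.05), 1 for each TPA effect (5 without and 7 with BRAF) and 0 for the interaction (1; 2 at an unadjusted p under 0.05). For the BRAF effect without TPA, 3 lists were called with a replicate block and 2 with library totals.

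Of the values of named miRNAs that were called, 2156 kept direction and call under alternatives with all libraries, 116 lost the call and 5 reversed; with a library left out, 905 kept it and 223 lost it. Of those not called, 159 and 33 gained a call, and 4 reversed. All reversals came with library totals only, which shifts the median of all miRNAs by -0.51 and -0.39 (log2) in the TPA effects. For the TPA effect without BRAF the reversed log2 changes were miR-514a-3p -0.357, let-7f-5p -0.451, miR-93-5p -0.174, miR-25-3p -0.177, miR-16-5p -0.287, miR-148b-3p -0.439 and miR-10a-5p -0.044, and for that with BRAF miR-15a-5p -0.008 and miR-34a-5p -0.067. In simulated data 1.5-fold changes were recovered in 35.8% of cases for the BRAF effect with TPA and 22.4% for the interaction. Smaller differences were thus often not detectable. The simulated data held more changed miRNAs than either comparison called, so recovery in the real data may be lower.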

Other observations

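From the miR-17-92 cluster on chromosome 13, miR-20a-5p (MIR20A, 91351065 to 91351135) was 1.97-fold higher with TPA than without it in cells without BRAF and 1.75-fold higher in cells with BRAF, while its paralog miR-20b-5p, from chromosome X (MIR20B, 134169809 to 134169877), was 2.36-fold and 3.804-fold lower with TPA in the same comparisons; both kept these calls under all 19 alternatives run. miR-363-3p, from the same X-linked cluster and chosen after its values were seen, had log2 changes with TPA of -1.19 and -1.47 and was called in both by edgeR's quasi-likelihood test. The difference between the members on the 2 chromosomes was not tested. Over the miR-17-92 list, 10 of 24 tested members rose and 7 fell with TPA in cells without BRAF (camera adjusted p = 0.271), and 8 rose and 6 fell with TPA in cells with BRAF (camera adjusted p = 0.819). These paralogs share much of their sequence, so reads may be split between them, a source that fractional counts (246 called for the TPA effect without BRAF, against 244) do not address.

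In the let-7 family, 3 of 20 members rose and 9 fell with TPA without BRAF (the same counts when adjusted over the list alone; camera adjusted p = 0.394). let-7i-5p, the most abundant, was 1.63-fold higher, a call that ended with library totals, and let-7a-5p was 1.34-fold lower, a call that ended in a fit of the compared groups only and without TPA no BRAF replicate 1 or 2. Of the keratinocyte and epithelial markers, 2 of 5 rose and 1 fell with TPA in cells with BRAF (camera adjusted p = 0.287): miR-141-3p was 2.80-fold and miR-200a-3p 2.53-fold higher (n = 3 each), and miR-203a-3p was 2.40-fold lower.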
